A study of Arabidopsis thaliana with 18 samples.

How the data were processed

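RNA from Arabidopsis thaliana of the accession Cvi-1 was measured on 18 Affymetrix ATH1 arrays, 1 array per sample. Per the labels, 9 samples had received 0.02% silwet, an organosilicone surfactant, and 9 had received 0.30 mM salicylic acid (SA) in 0.02% silwet. The titles give replicate numbers 1 to 3, and each number occurs 3 times in each treatment. What separates those 3 arrays is not given in the sources used here, nor are the tissue and the time of harvest, and none was inferred. The titles also carry an identifier that is not explained, which runs in separate ranges for replicates 1, 2 and 3, and it entered no test. Arrays are named here by the serial number in their title, which is 19 to 27 for silwet and 28 to 36 for SA.

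The authors deposited 1 table of signal intensity per probe set, made with MAS5 per the submitters' processing notes, whose version and settings are not given in the sources used here. Its values are linear, positive and complete over 22810 probe sets, with 0 missing values. Each column had a 2% trimmed mean of 100.01, so the deposited intensity values were taken as scaled already and no further scaling between arrays was applied. MAS5 signal is most variable at low intensity, where log2 differences are the least precise, and a scaled mean hides any change in total RNA. Of the columns in the table, 0 lacked a sample.

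The 64 control probe sets were left out, and log2 of the signal was taken with no pseudocount. A probe set was tested when its mean log2 signal over the 18 arrays was at or above the 40th percentile, which was 4.31 (a signal of 19.9), and 13648 passed. The platform annotation paired 13513 probe sets with 1 gene, 503 with several and 8730 with none, and symbols were updated through the TAIR10.1 gene table. Of the tested probe sets 7342 had 1 gene and 6306 had several or no named gene. A probe set without a single gene name was not named. PR1, PR2, PR5, ICS1, NPR1 and WRKY70, which the rule for named genes includes, had no probe set of their own in that annotation and are not reported here.

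SA was compared with silwet in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, over 9 arrays against 9 and without a term for the replicate number. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. A 6-group limma model gave the SA difference within each replicate number (3 arrays against 3) and an F-test of whether it differed between numbers. A further F-test with treatment in the model compared the 3 replicate numbers, 6 arrays each. For gene lists, the same model also gave each pair of replicate numbers as a contrast, adjusted over all probe sets within that contrast. Gene lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. A gene with more than 1 tested probe set was represented by the one with the highest mean log2 signal. Principal components were taken from the log2 signal of the tested probe sets after centring each. A list's median loading on the first component (log2 signal per unit of score) was ranked among 10000 random lists of the same size matched on mean level, and so was its median correlation with the score. The loading replaced the correlation as the first measure after the correlation ranks had been seen, and both ranks are given.

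The tests, the filter, 19 gene lists holding 306 genes, the rule for named genes and the alternative settings were fixed before the data were examined. The rule took the 12 largest higher and lower calls with the same sign in every replicate number, the 6 genes above, and up to 4 called members of each list, or, where none was called, the 2 members with the smallest p. Of the 306 list genes 40 had a probe set of their own and 34 were tested. For that reason 31 gene families defined by symbol, locus or gene type were added after the annotation had been read and before any test was run, and 30 of them had enough members. WRKY53, the genes with the smallest p and the genes named for the replicate numbers and for the first component were chosen after their values were seen.

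The alternatives were a pseudocount of 8.06, no filter, a filter at the 60th percentile, quantile normalization, median centring, no intensity trend, array weights, leaving out each replicate number, the replicate number as a fixed or random block, and the first residual component as a covariate. Leaving out single arrays, and the bioB signal, the 3' to 5' control ratios and the share of probe sets with a signal under 16 as covariates for the replicate numbers, were added after seeing the data. The same code was tested on simulated data with the real means and spreads of 13648 probe sets, of which 200 were changed. For SA against silwet it recovered 47.5% of 1.5-fold, 86.0% of 2-fold and 98.5% of 4-fold changes. Within replicate 1 it recovered 0% of 1.5-fold, 44.5% of 2-fold and 86.0% of 4-fold changes. For the replicate numbers the shares were 18.5%, 76.5% and 96.0%. For an SA effect in 1 replicate number only, the F-test recovered 0%, 10.5% and 70.5%. The simulated spreads were independent between probe sets. They were what remained after removing treatment and replicate number, and the simulated arrays held no other replicate differences and no arrays set apart. The real data hold both, so the recovered shares may be too high for them. Files were read with Python 3.11.15 and pandas 2.3.3.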

Results

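Transcript levels were measured in 18 samples of the Arabidopsis accession Cvi-1, from the Cape Verde Islands, to compare salicylic acid (SA), a hormone of plant defence, in the surfactant silwet with silwet alone. The 9 arrays of each treatment carry the replicate numbers 1, 2 and 3, with 3 arrays for each number. Median signal per array ranged from 31.7 to 38.7 after the authors' scaling, and the number of arrays limits the precision. No label says whether the arrays came from separate plants, so the p-values measure the spread between these samples, which may be technical. What separates the 3 arrays of a replicate number within a treatment is not given in the sources used here. If they differ in harvest time or another condition, that difference is part of every pooled SD and SE, and an SA effect limited to some of them could be missed by the pooled test.

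The SA marker genes were high in 3 arrays, 2 of them from SA and 1 from silwet. UGT76B1 (AT3G11340), a glycosyltransferase that conjugates SA, had a signal of 1240 in array 28 (SA, replicate 1) and 1550 in array 30 (SA, replicate 3), against 10.3 to 54.0 in the other 7 SA arrays. In silwet its signal was 1540 in array 20 (replicate 2) and 10.6 to 77.6 in the other 8 arrays. GRX480 (AT1G28480), a glutaredoxin that binds TGA transcription factors, had signals of 613 and 701 in arrays 28 and 30 and 733 in array 20, and at most 201 elsewhere. WRKY53 (AT4G23810), a transcription factor of senescence and defence, had 715 and 511 in arrays 28 and 30, its highest silwet signal in array 20, and at most 232 in the other arrays.

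**Figure D1:**
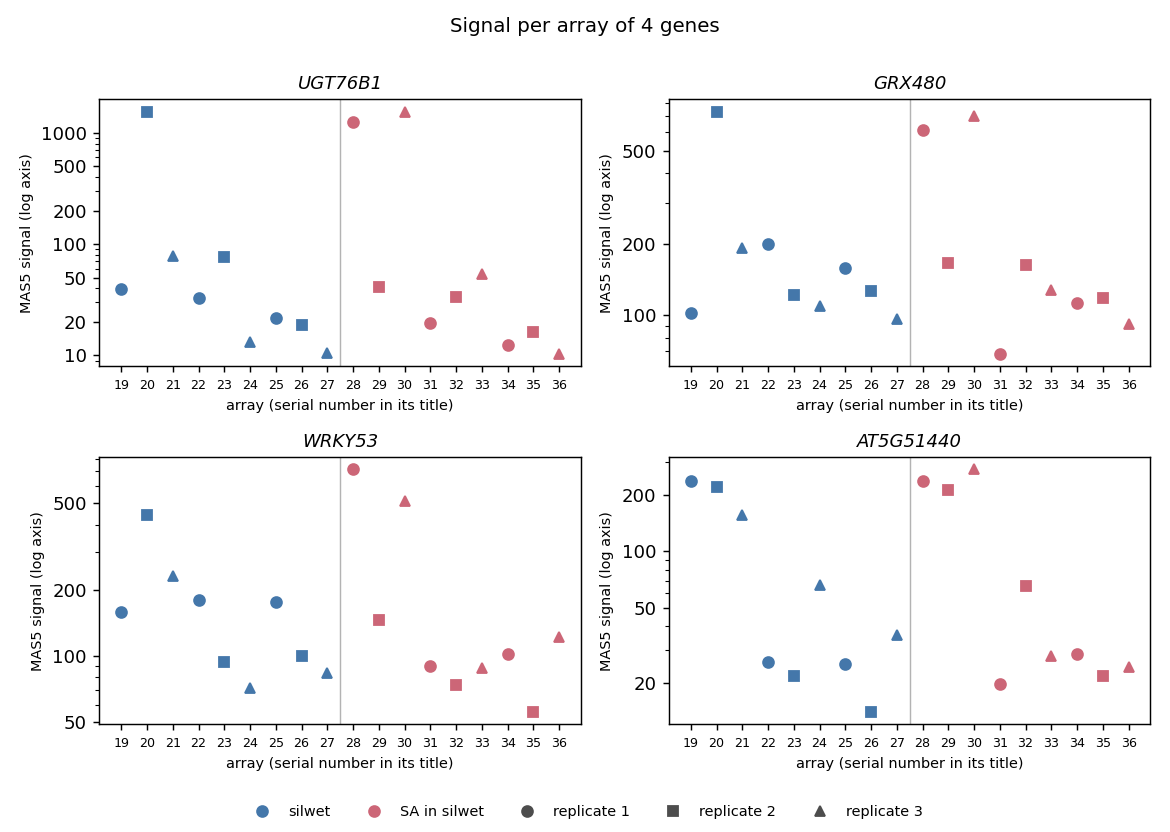
MAS5 signal (log axis) of UGT76B1, GRX480, WRKY53 and AT5G51440 in each array, plotted by the serial number in its title. Each point is 1 array, coloured by treatment and shaped by replicate number, with a vertical line between silwet and SA. UGT76B1 reached 1540 in array 20, 1240 in array 28 and 1550 in array 30, and AT5G51440 lay between 156 and 273 in arrays 19, 20, 21, 28, 29 and 30.

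Between the treatments as labelled, these genes differed by less than their spread. Mean UGT76B1 signal was 331 ± 609 (SD, n = 9) in SA and 203 ± 502 (SD, n = 9) in silwet, a log2 difference of 0.34 (SE 1.05). GRX480 averaged 240 ± 239 (SD, n = 9) in SA and 204 ± 202 (SD, n = 9) in silwet, a log2 difference of 0.08 (SE 0.45). For WRKY53 the log2 difference was -0.05 (SE 0.46). The limma adjusted p was 1 for each. Without array 20 the log2 differences were 0.98 for UGT76B1 and 0.36 for GRX480 (limma adjusted p = 0.988 for both) and 0.15 for WRKY53 (limma adjusted p = 0.99). The list of SA markers, with 3 members tested, had a median log2 difference of 0.08, and camera gave an adjusted p of 0.821, or an adjusted p of 0.878 with an estimated correlation.

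Other defence genes gave similarly small differences, and 0 members of any list were called, whether adjusted over all probe sets or adjusted over the list alone. SAG101, a lipase-like partner of EDS1, differed by 0.13 log2 (SE 0.18). The receptor EFR differed by 0.02 (SE 0.18), and the kinase BIK1 by 0.00 (SE 0.29). GSTU25, a glutathione transferase of the detoxification list, differed by 0.09 (SE 0.34). For protein folding in the ER, the log2 differences were -0.14 (SE 0.17) for the calreticulin CRT2 and 0.07 (SE 0.21) for ERDJ3B. UGT74B1 of indole glucosinolate synthesis differed by 0.04 (SE 0.17) and BCAT4 of aliphatic glucosinolate synthesis by -0.08 (SE 0.14). BIK1 had its highest signals, 324, 245 and 355, in arrays 20, 28 and 30, and at most 211 elsewhere. ERDJ3B had 1060, 924 and 1040 there and at most 690 elsewhere. Without array 20 the log2 differences were 0.20 for SAG101, 0.07 for EFR, 0.15 for BIK1, 0.25 for GSTU25, -0.07 for CRT2, 0.19 for ERDJ3B and 0.14 for UGT74B1, and limma called 0 of them.

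Single genes of photosynthesis and growth gave no call either. The photosynthesis list, with 8 members, had a median log2 difference of -0.04 (camera adjusted p = 0.406, or adjusted p = 0.878 with an estimated correlation). The sign of its median was not stable: camera called the list in opposite directions without replicate 1 (median 0.04, adjusted p = 0.0248, or adjusted p = 0.825 with an estimated correlation) and without replicate 2 (median -0.13, adjusted p = 0.00233, or adjusted p = 0.502). With quantile normalization it was called at a median of -0.05 (adjusted p = 0.00311, or adjusted p = 0.137 with an estimated correlation). The antenna protein gene LHCB4.1 differed by -0.10 (SE 0.07) and Rubisco activase, RCA, by -0.12 (SE 0.09). The auxin response list, with 3 members, had a median of -0.09 (camera adjusted p = 0.837, or adjusted p = 0.878 with an estimated correlation), with IAA29 at -0.14 (SE 0.41) and GH3.5 at -0.06 (SE 0.35). The expansin genes EXPA8 and EXPA4 differed by -0.41 (SE 0.44) and -0.07 (SE 0.20). In senescence, SAG29 differed by -0.31 (SE 0.73) and WRKY6 by 0.09 (SE 0.33). The clock gene GI differed by -0.31 (SE 0.25). The list of abscisic acid (ABA) and cold genes, with 4 members, had a median of -0.05 (camera adjusted p = 0.821, or adjusted p = 0.878 with an estimated correlation), with LTI30 at -0.11 (SE 0.19) and COR47 at -0.05 (SE 0.13). The reference genes, with 3 members, had a median of -0.11 (camera adjusted p = 0.406, or adjusted p = 0.723 with an estimated correlation), with TIP41 at -0.13 (SE 0.09) and SAND at -0.11 (SE 0.10). Without array 20 the differences were 0.09 for GH3.5, -0.21 for IAA29, -0.14 for EXPA4, 0.32 for WRKY6 and -0.11 for COR47, and limma called 0 of them. None of the genes on the jasmonate and ethylene, heat stress, cell cycle, root, and flower and seed lists was tested. The root genes EXPA7 and EXPA18 had signals of at most 16.3 in every array.

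Among gene families defined by name, camera called 2 of 30. The ubiquitin-conjugating enzymes (10 members) had a median log2 difference of 0.07 and the autophagy genes (8 members) one of 0.10, both with a camera adjusted p of 0.0106. With an estimated correlation the adjusted p was 0.902 for both, and 0 families were called. Both medians kept their sign under quantile normalization and median centring. The photosystem and light harvesting genes (16 members) had a median of -0.09 (camera adjusted p = 0.168, or adjusted p = 0.97 with an estimated correlation), and camera called them too, 3 families in all, with quantile normalization, without replicate 2, without array 20 and without arrays 20 and 29. Their median was -0.13 without array 20 (adjusted p = 0.0324, or adjusted p = 0.759 with an estimated correlation), but 0.02 without replicate 1. With an estimated correlation, the camera adjusted p was 0.636 with quantile normalization, 0.814 without replicate 2 and 0.811 without arrays 20 and 29. Without arrays 20, 28 and 30, without replicate 1 and without replicate 3 camera called 0 families at the preset correlation.

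Over all 13648 probe sets limma called 0, with a smallest adjusted p of 1, and 94 had an unadjusted p under 0.05 where chance alone would give 682. The median SE was 0.16 log2, and the 95% interval of the difference lay within 2-fold for 96.8% of probe sets and within 1.5-fold for 78.0%. The model held no term for what separates the 3 arrays of a number within a treatment, nor for arrays 20, 28 and 30. Any such difference is part of these SEs. The 0 calls and the count below chance therefore do not show that SA had no effect. The gene with the smallest p, AT5G18420, had a log2 difference of 0.34 (SE 0.10, limma adjusted p = 1). CYP59 had one of -0.50 (SE 0.17, limma adjusted p = 1). Without array 20 limma also called 0, with 232 at an unadjusted p under 0.05, and without arrays 20, 28 and 30 it called 0, with 245.

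**Figure D2:**
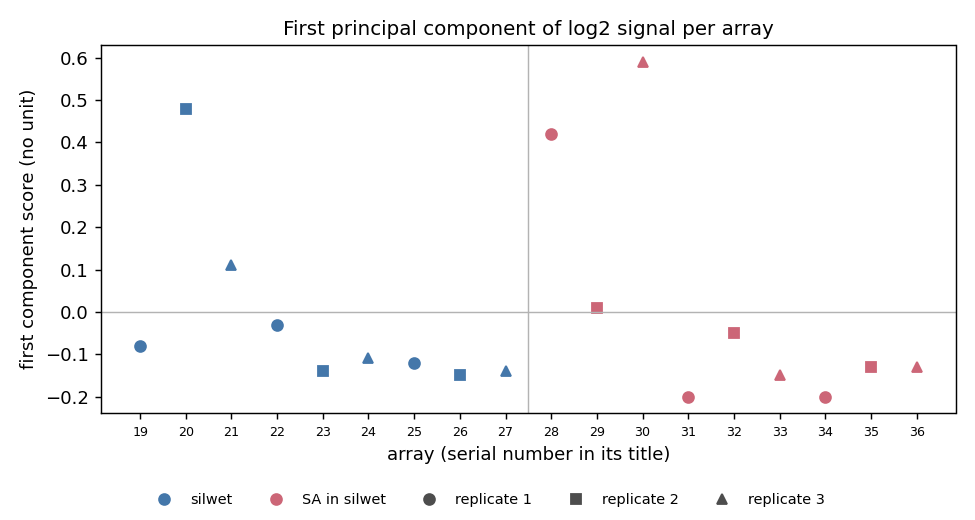
Score of each array on the first principal component of log2 signal (no unit), which held 43.9% of the variance, plotted by the serial number in its title. Each point is 1 array, coloured by treatment and shaped by replicate number. Arrays 20, 28 and 30 lie at 0.48, 0.42 and 0.59, and the other arrays between -0.20 and 0.11.

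Within each replicate number, where 3 SA arrays met 3 silwet arrays, the SA marker genes gave differences of either sign, none past the threshold. The log2 difference of UGT76B1 was 1.13 in replicate 1, -2.21 in replicate 2 and 2.1 in replicate 3 (SE 1.88 each). For GRX480 the differences were 0.17, -0.60 and 0.67 (SE 0.84), and for WRKY53 0.12, -0.93 and 0.66 (SE 0.82). In replicate 1 LHCB4.1 differed by -0.37 (SE 0.11) and RCA by -0.38 (SE 0.15), against 0.13 and 0.11 in replicate 2 and -0.07 and -0.09 in replicate 3. Limma called 0 probe sets in each number, with 213, 84 and 113 at an unadjusted p under 0.05 in replicates 1, 2 and 3. The test of whether the SA effect differed between numbers also called 0, with 118 at an unadjusted p under 0.05. Without array 20 limma called 0 in replicate 2 and 0 in the test between numbers, with 69 and 63 at an unadjusted p under 0.05. Across probe sets, which are not independent replicates, the SA differences of replicates 1 and 3 correlated at 0.46, those of replicates 1 and 2 at -0.35 and those of replicates 2 and 3 at -0.48. Without array 20 the correlations of replicate 2 were 0.06 with replicate 1 and 0.22 with replicate 3.

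Replicate 1 was the highest or the lowest of the 3 numbers in 392 of the 400 probe sets that limma called, highest in 241 and lowest in 151. That share of 98% compares with 81.0% over all tested probe sets. The count was 609 with median centring, 1417 with array weights, 209 with a filter at the 60th percentile and 744 without arrays 20, 28 and 30. The share of probe sets with a signal under 16 was 37.6% ± 1.07, 35.9% ± 1.09 and 35.0% ± 1.35 (SD, n = 6) in replicates 1, 2 and 3 (two-sided exact permutation test, p = 0.00733, adjusted over 4 measures 0.0293). The 3' to 5' ratio of the ubiquitin control was 3.36 ± 0.386, 2.95 ± 0.433 and 2.80 ± 0.189 (SD, n = 6; exact permutation test, p = 0.0509, adjusted 0.102), which did not pass, and neither did the ratios of GAPDH (adjusted exact p = 0.344) and actin (adjusted exact p = 0.891). Mean log2 signals are given for replicates 1, 2 and 3 in that order, with n = 6 arrays each, and adjusted p-values are those of limma's F-test over the 3 numbers. AT1G66100 had 6.61 ± 0.55, 8.79 ± 0.36 and 8.5 ± 0.37 (SD, adjusted p = 0.000533). The thionin gene THI2.2 had 7.86 ± 0.45, 9.11 ± 0.33 and 9.44 ± 0.14 (adjusted p = 0.0011). The drought-induced gene DI21 had 7.19 ± 0.83, 5.38 ± 0.33 and 5.45 ± 0.31 (adjusted p = 0.00608). AT1G80130 had 8.76 ± 0.81, 6.79 ± 0.20 and 7.01 ± 0.31 (adjusted p = 0.00311).

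The 4 genes of the ABA and cold list had a median log2 difference of -0.52 between replicates 3 and 1, with 2 of 4 members called lower in that pairwise limma contrast (1 by the F-test over the 3 numbers) and a camera adjusted p of 0.00847 over 105 tests of lists and families. With an estimated correlation the adjusted p was 0.538. COR15A, which encodes a cold-regulated chloroplast protein, had 11.10 ± 0.24, 10.51 ± 0.24 and 10.18 ± 0.31 (SD, n = 6, limma F-test adjusted p = 0.0101). The 65 tested genes of the chloroplast genome differed between replicates 3 and 1 by a median of 0.66 log2 and by -0.38 to 2.35 singly, with 17 called higher in the pairwise contrast (10 by the F-test) and a camera adjusted p of 1.16e-16, or an adjusted p of 0.814 with an estimated correlation. Against replicate 2 their median difference was 0.58 with 0 called in the pairwise contrast (camera adjusted p = 3.48e-38, or adjusted p = 0.506 with an estimated correlation). The ATP synthase gene atpF had 7.40 ± 0.55, 7.21 ± 0.91 and 9.42 ± 0.73 (SD, n = 6, limma F-test adjusted p = 0.0125). The cytochrome b6f gene petL had 8.19 ± 0.37, 8.25 ± 0.73 and 9.47 ± 0.25 (SD, n = 6, limma F-test adjusted p = 0.0181). The signs of these medians were the same under quantile normalization and median centring.

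**Figure D3:**
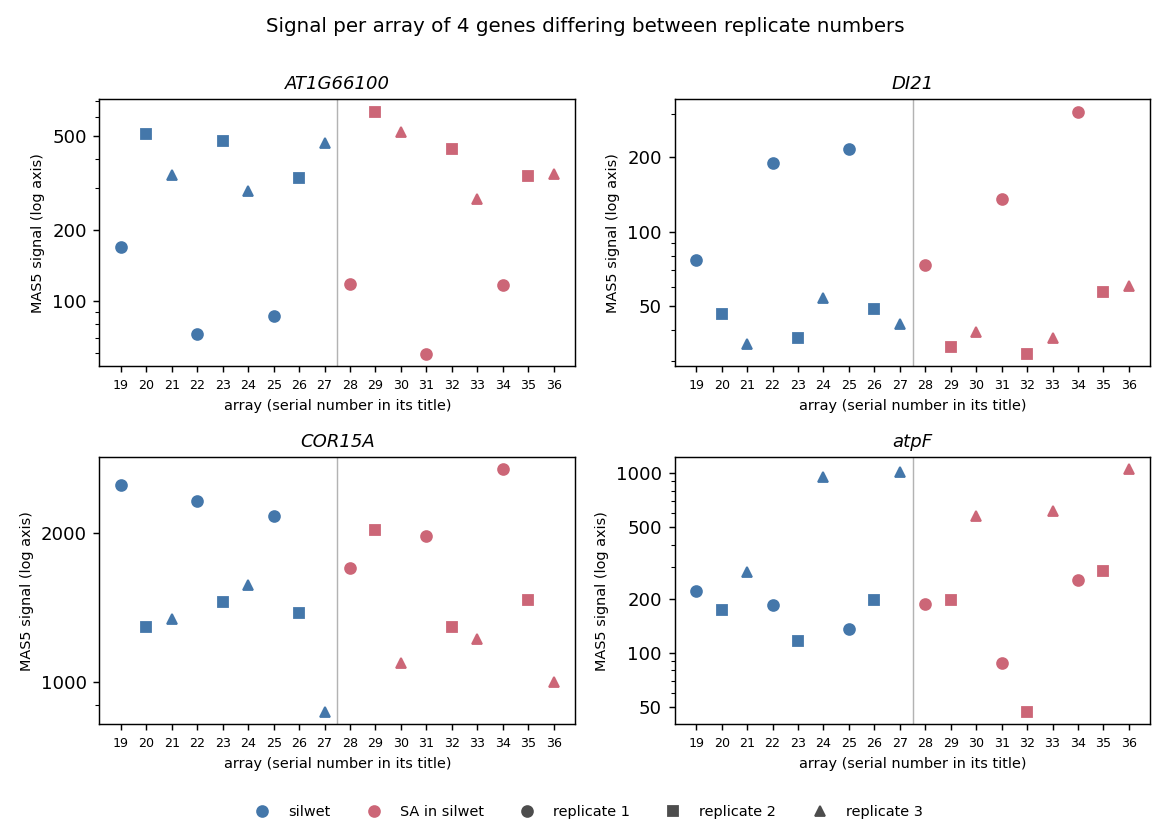
MAS5 signal (log axis) of AT1G66100, DI21, COR15A and atpF in each array, plotted by the serial number in its title. Each point is 1 array, coloured by treatment and shaped by replicate number. AT1G66100 lay between 59.6 and 169 in the 6 arrays of replicate 1 and between 269 and 633 in the other 12 arrays.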

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

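The tests of explanations and the comparisons with other splits were chosen after the results they bear on were seen. Among 91 groups of arrays examined for a sample far from the others, 6 had one. Chance alone would flag about 1 in 20 independent groups, and the number flagged is near that rate. But the groups reuse the same arrays, and their genes can vary together, so that rate does not tell whether the flags arose by chance. The flags were not scattered over the arrays. In 5 of the 6 flagged groups the far sample was array 20, the highest of the 9 silwet arrays. Its gap to the next array, as a share of the range, was 0.6 for UGT76B1, 0.637 for GRX480, 0.507 for CRT2, 0.503 for WRKY6 and 0.587 for the score on the first component. Array 29 (SA, replicate 2) was the highest of the 6 arrays of replicate 2 for COR15A, with a gap of 0.727 of the range.

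Array 20, labelled silwet, correlated best with array 30 (r = 0.84 across probe sets), and array 28 correlated best with array 20 (r = 0.71). SA treatment was not tested as a cause, since these arrays were singled out by their scores, and the other 15 arrays, 7 of them from SA, scored at most 0.11. RNA degradation is argued against: only 1 of 9 ratios of 3' to 5' control signal in these 3 arrays lay above all other arrays. Array scaling is argued against by the score of array 20 after quantile normalization, 0.47. A wrong label on array 20 may explain its place and stays open: exchanging its label with that of an SA array gave up to 1600 probe sets at an unadjusted p under 0.05, but a split that joins 3 arrays already seen to be alike raises the count by construction, and 0 of 81 exchanges gave a limma call.

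The SA differences of replicate 2 ran against those of replicates 1 and 3, and this depended on array 20. Without it the correlation of replicates 2 and 3 went from -0.48 to 0.22. Leaving out any other array of replicate 2 left that correlation between -0.60 and -0.38. Leaving out SA arrays 28 (replicate 1) and 30 (replicate 3), which share the high first component score of array 20, was not tried. Array 20 is therefore not shown to act alone, and the correlation of replicates 1 and 3 was not taken without arrays 28 and 30. No biological explanation was tested. The titles carry a further identifier in separate ranges for the 3 numbers, and no label says what it or the number stands for.

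Of 100 splits of the arrays into replicate numbers, 2 gave as many probe sets as the real 400, the real one included. That share is under 0.05 and argues against chance as the source, but 100 splits do not exclude it. The highest other split gave 884 and put arrays 20, 28 and 30 under 1 number, which points to the structure of the samples. The bioB hybridisation control averaged 26.8 ± 5.36, 43.5 ± 6.99 and 30.1 ± 8.60 (SD, n = 6) in replicates 1, 2 and 3 (exact permutation test, p = 0.00655, adjusted over 2 controls 0.0131). Hybridisation strength as read from bioB is argued against as the only cause. The control put replicate 3 near replicate 1, while 25 of the 400 probe sets had replicate 3 nearer replicate 1 than replicate 2. Over all tested probe sets that share was 30.6%. With log2 bioB as a covariate, the test run first, limma called 163, 153 of them among the 400. A part in the pattern therefore stays open, since bioB itself differs between the numbers and the covariate cannot tell them apart. RNA quality may account for part of the pattern and stays open: with log2 of the ubiquitin control's 3' to 5' ratio as a covariate limma called 142. But that ratio's own difference between the numbers did not pass, and with the GAPDH or actin ratio limma called 426 or 567. The share of probe sets with a signal under 16 did differ between the numbers, and with its log2 as a covariate limma called 434. A difference in growth or harvest between the numbers was not tested.

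For SA against silwet the real count was 0, which 100 of 100 splits must reach, so this says nothing about chance, and the highest other was 1. At an unadjusted p under 0.05 the real split gave 94, 99 of 100 splits gave as many, and the highest other gave 2715, which points to the same structure. For the 2 name families called, 55 of 100 splits gave as many, with a highest other of 9, so chance is not excluded. For the SA effect differing between numbers the real count was also 0, reached by 100 of 100 splits whatever the data, with a highest other of 2. Within replicates 1, 2 and 3, 10 of 10 splits each gave as many as the real 0, with a highest other of 0, and 10 splits are too few for a share under 0.05.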

How the results depend on the processing

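The removals of single arrays were chosen after seeing the data, and the name families after the annotation was read. For SA against silwet limma called 0 probe sets, 0 higher and 0 lower, under all 16 alternatives. The count at an unadjusted p under 0.05 was lowest, at 29, without replicate 3, highest without arrays 20 and 29, and below 682 in each. The 682 is the chance figure for the 13648 probe sets of the main filter. No filter tests more probe sets (a count of 334) and the 60th percentile filter fewer (42), so their chance figures differ. With the replicate number as a replicate block, fixed or random, the count was 0, with 131 and 111 at an unadjusted p under 0.05. Deviations of same-numbered arrays correlated at 0.73, 0.03 and 0.48 in replicates 1, 2 and 3. The 0.03 fell short of the 0.1 asked of every number before the numbers were taken to pair the arrays. Replicate 2 holds array 20, and this check was not repeated without it. Still, 12 of 18 arrays correlated best with an array of their own number, a hint from the data that the numbers mark shared structure. The block changed no other call. Camera could not be run with the random block. Low signal limits the differences of weak probe sets.

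Within replicate 1 limma called 1 probe set with no filter. Fixed gene lists called numbered 1 with quantile normalization (photosynthesis) and ranged from 0 to 2 when a replicate number was left out (photosynthesis higher without replicate 1 and lower without replicate 2, reference genes lower without replicate 1), and 0 of these calls held with an estimated correlation. Name families called numbered 0 with no filter, with array weights, without arrays 20, 28 and 30 and with an estimated correlation, and ranged from 0 to 3 when a replicate number was left out. The photosystem and light harvesting genes were added with quantile normalization, without replicate 2, without array 20 and without arrays 20 and 29. Each of these added calls was lost with an estimated correlation. The probe sets differing between replicate numbers were 209 with the 60th percentile filter, which tests fewer, 609 with median centring, 1417 with array weights and 744 without arrays 20, 28 and 30. The cause of the other changes was not tested.

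Of 377 values of the 24 named genes under the alternatives, 36, of 16 genes whose log2 difference was at most 0.34 in size, changed sign and 0 were called. The 377 include settings that leave a log2 difference unchanged by construction. These are both changes of filter, no intensity trend, either replicate block and the first residual component. The share that changed sign is therefore higher among the values that could. BIK1 went to 0.01 with quantile normalization and 0.03 with median centring. With array weights the log2 differences were -0.01 for GRX480, 0.27 for GSTU25, -0.04 for EFR, 0.02 for BCAT4, 0.01 for IAA29, 0.12 for GH3.5 and 0.03 for EXPA4. Without array 20 they were 0.98 for UGT76B1, 0.36 for GRX480, 0.32 for WRKY6, 0.15 for BIK1, 0.09 for GH3.5 and 0.15 for WRKY53, and without arrays 20 and 29 1.04, 0.36, 0.27, 0.09, 0.02 and 0.15. Without arrays 20, 28 and 30 they were -0.34 for UGT76B1, -0.20 for GRX480, -0.03 for ERDJ3B, -0.07 for EFR, 0.05 for BCAT4, 0.05 for EXPA4 and 0.32 for SAG29. When a replicate number was left out, the log2 difference ranged from -0.54 to 1.62 for UGT76B1, -0.21 to 0.42 for GRX480, -0.12 to 0.35 for GSTU25, -0.16 to 0.19 for EFR, -0.12 to 0.15 for BIK1, -0.12 to 0.15 for UGT74B1, -0.22 to 0.06 for BCAT4, -0.22 to 0.03 for LHCB4.1, -0.24 to 0.01 for RCA, -0.27 to 0.09 for IAA29, -0.19 to 0.08 for GH3.5, -0.19 to 0.09 for EXPA4, -0.06 to 0.27 for WRKY6 and -0.40 to 0.39 for WRKY53. The cause was not tested.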

Other observations

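The genes and families described here were chosen after their values were seen, and the values are given per array with no test between arrays. The first component, on which arrays 20, 28 and 30 stood apart, was set against 35 gene lists and families. Each was ranked among random lists both by its members' median loading (log2 signal per unit of score) and by their median correlation with the score. Genes of a list can vary together, which random lists do not copy, so an extreme rank is not a test. The ranks were not adjusted over the lists. The correlation was computed first, and the loading was put first after those ranks had been seen. The 3 arrays set apart from the rest dominate both measures. The 3 SA markers had a median loading of 4.03, above 100% of random lists by either measure. The auxin response list (3 members) had 2.51, above 99.6% by loading and 98.1% by correlation, though its members went both ways, with GH3.5 at 2.51 and IAA29 at -1.24, and the family of Aux/IAA and GH3 genes (3 members) had 0.47, above 83.7% and 83.4%. The calmodulin-like genes (3 members) had 1.99, above 98.6% and 94.5%. The WRKY transcription factors (5 members) had 1.93, above 99.7% by loading and 99.5% by correlation. The plant U-box and ATL ubiquitin ligases (7 members) had 0.95, above 98.6% and 99.5%, and the genes of vesicle traffic (27 members) 0.55, above 99.9% and 100%. On the other side lay the expansins (8 members), with -1.72, above 0% of random lists by loading and 1.5% by correlation, and the serine carboxypeptidase-like genes (14 members), with -1.07, above 0.2% and 0.8%. The histones (4 members) had -1.22, above 2.6% and 4.4%, and the cytochromes P450 (8 members) -0.88, above 2.4% and 1.2%. Of the other lists fixed before the data were examined, photosynthesis lay above 70.7% and 41.7%, ABA and cold above 45% and 72.7% and the reference genes above 58.4% and 58.9%. The median over all tested probe sets was -0.21. The place of the photosystem and light harvesting genes (16 members) depended on the measure: their median loading of -0.42 lay above 30.1% of random lists, and their correlation above 2.4%. The chloroplast genome genes (65 members) lay above 64% by loading and 94.3% by correlation. AT4G24780 had signals of 162, 182 and 68.5 in arrays 20, 28 and 30 and at least 394 in each other array. AT5G03350 had 1690, 1310 and 1420 there and at most 260 elsewhere.

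A different pattern, seen in AT5G51440 and AT3G16530 among other genes, parted 6 arrays from the rest. They were 3 of each treatment and 1 of each replicate number within it. AT5G51440 had signals of 238, 219 and 156 in silwet arrays 19, 20 and 21 and of 238, 213 and 273 in SA arrays 28, 29 and 30, and at most 65.9 in the other 12 arrays. AT3G16530 had 717, 982 and 478 in arrays 19, 20 and 21 and 1210 and 972 in arrays 28 and 30, and at most 211 in those 12, with array 29 in between. AT1G52200 had 370, 1410 and 778 in arrays 19, 20 and 21 and 1090, 598 and 1460 in arrays 28, 29 and 30. It had at most 347 in those 12. No label says what these 6 arrays share. Their titles hold the 3 lowest serial numbers of each treatment and, within each replicate number, the lowest values of a further identifier that is not explained, and no condition was inferred from either. Of them, UGT76B1 was at 39.3, 77.6 and 41.2 in arrays 19, 21 and 29. Array 29 is labelled SA, and its nearest array was array 19, from silwet (r = 0.32 across probe sets). A hypothesis is that arrays 20 and 29, both of replicate 2, may have exchanged labels. Exchanging them gave 0 limma calls and 806 probe sets at an unadjusted p under 0.05. Exchanging arrays 20 and 31 gave 1600, but that puts arrays 20, 28, 29 and 30 of these 6 together on the SA side. The pattern of the 6 arrays then enters the comparison, so ranking these counts says nothing for or against array 29. Any exchange that moves array 20 beside arrays 28 and 30 raises the count by construction, and the bounds for reading it were set after it was known, so this count does not decide.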
